A study of Xenopus tropicalis with 40 samples.

How the data were processed

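The series covers polyadenylated RNA from Xenopus tropicalis embryos, sequenced as 40 libraries of 23 developmental stages in 2 clutches. Per the labels' protocols, the libraries were made so that the strand of the RNA was kept. The submitters' processing notes name Bowtie, TopHat and Cufflinks, which align reads to a genome, align reads across splice junctions and assemble transcripts. Their versions, their order, the genome build and the gene annotation are not given in the sources used here.

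Both tables used here describe 1 assembly pooled over the whole series. One deposited table lists each assembled transcript with a length, a value headed FPKM and a coverage. The values headed FPKM are a score deposited by the authors and not an abundance: none exceeds 1, 58.9% equal exactly 1, and both confidence bounds are 0 in all 167756 rows. This score is called the relative weight of a transcript below. The deposited coverage is a signal between 0 and 10.2 that is 0 for all 3525 models taken over from the annotation, and it is not read depth. The deposited gene models give scaffold, strand and exon ends of 159469 transcripts, with a code for their relation to the annotated genes and the symbol of the annotated gene. Coding start and end equal the transcript ends in every model, so untranslated regions could not be measured. Positions are printed counted from 1, while the gene models count starts from 0, on scaffolds of a build that the sources used here do not name.

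No value per library, stage or clutch was analysed here, so the tests between stages and between clutches that had been fixed were not run, and no library depth is known. The catalogue itself was analysed. The planned rule for a single pooled column relied on FPKM; because the column is no abundance, genes were ranked by their number of multi-exon isoforms instead. The rule for named genes was the 10 genes with a symbol and the most multi-exon isoforms, the 4 members with the most isoforms per gene list, and every list member represented only by an annotated model. The rule left out genes with a provisional symbol in the gene models, among them LOC496414 with 678 isoforms (col1a1 in the RefSeq table), more than any named gene, and LOC100216130 with 248 (tcof1). Some genes that the rule names are not reported here. The part of the rule that took the genes and the transcripts of each class with the highest FPKM was dropped. Genes named for antisense transcripts, for Hox loci, for families and for loci outside annotated genes were chosen after their values were seen.

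The tests of list isoform numbers, of annotated models only, of antisense transcripts, of splicing events and of exon lengths divisible by 3 were added after the files had been examined, and the fixed list rule by FPKM was not used. List names were at first also matched through synonyms, which gave wrong genes such as fzr1 for cdh1. The matching was corrected after list results had been seen, and the call of the skeletal muscle list depends on it.

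Transcript classes follow the Cufflinks class codes. Annotated genes are those with a transcript on their own strand that matches the annotated junction chain, has a new junction chain or overlaps an exon otherwise. A model counted as assembled when its identifier was a number given by the assembler, and as an annotated model only when it carried the name of the annotation. Whether reads covered the latter is not recorded. Isoforms per gene are assembled transcripts with at least 2 exons. The exon number of a gene is the largest among its transcripts. Splicing events were called per locus from the exon ends of all transcripts with at least 2 exons, annotated models included. The kinds were skipped exons, alternative 5 prime and 3 prime splice sites, retained introns, mutually exclusive exon pairs, and separate first and last exons. Skipped exons and exclusive pairs were counted by exact exon ends, so variants of the same exon with different ends count separately. A constitutive exon was an internal exon present in every transcript that spanned it, with at least 3 such transcripts. A microexon was an internal exon of at most 27 bases.

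Shares carry Wilson intervals at 95% confidence, which cover counting error only. Shares were compared with Fisher's exact test, and medians with a two-sided permutation test of 100000 resamples. Intervals for differences between exon sets came from 2000 bootstrap draws of whole loci, or 500 draws within size bins. Transcripts of 1 locus are not independent and no test here rests on replicate animals, so p-values describe the catalogue. The 20 gene lists were fixed before the data were examined. They hold 688 names, of which 426 had a model here, 13 of them under another symbol of the RefSeq table for assembly UCB_Xtro_10.0. That table was used for names only and matched 98.4% of the 8329 gene symbols. The median isoform number of each list, taken on the log2 scale, was compared with 100000 random lists matched on exon number, two-sided, and the p-values of the 20 lists were adjusted by the Benjamini-Hochberg method. Alternatives of the list test and the tests of explanations used 20000 random lists, and gene families 10000.

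The event caller was tested on simulated loci: it recovered 100% of 280 planted events and called 0 events of another kind. Each simulated locus held a few full-length transcripts and at most 1 event. The simulation therefore cannot show how the caller does at loci with many overlapping or partial transcripts. In 200 simulated comparisons without a difference, the permutation test of medians gave p under 0.05 in 6.5%, and in 90.5% with a simulated difference. With isoform numbers of 7418 real genes shuffled, the list test on lists of 20 genes found 55.0% of lists with a 2-fold change, 95.0% with a 3-fold change and 0.833% of unchanged lists. Alternatives limited the transcripts by exon number, length, relative weight or assembly, took 1 transcript per locus, left out loci with 50 or more transcripts or with several annotated genes, replaced list medians by means, or matched list names through synonyms too. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.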

Results

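Polyadenylated RNA of the western clawed frog Xenopus tropicalis was sequenced from the 2-cell embryo to the feeding tadpole of stages 44 and 45. The 40 libraries fall into 23 stages and 2 clutches of siblings. Clutch 1 gave 16 libraries of 14 stages and clutch 2 gave 24 libraries of 22 stages, with 13 stages in both. The values analysed here are 1 catalogue of transcripts pooled over all libraries, with 159469 transcripts at 31388 loci on 4044 scaffolds. The depth of the libraries is unknown, and no value belongs to a single stage or clutch, so what rose or fell during development was not analysed here. There are no replicates behind any value below.

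The first question was how much of the embryonic transcriptome lay outside the annotated genes. Most transcripts of annotated genes were splice variants that the annotation did not hold, as at hnrnpa1, an RNA-binding protein gene with 593 multi-exon isoforms, and col2a1, the cartilage and notochord collagen gene with 171. Nearly as many transcripts matched no annotated gene. The largest locus without an annotated gene, on the plus strand of scaffold GL173017 from 133541 to 210342, held 499 transcripts of up to 54 exons. Spliced RNA antisense to genes such as clk2, a kinase of splicing factors, formed a further class.

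Transcripts with a new junction chain in an annotated gene numbered 73288, or 46.0% of all (Wilson 95% interval 45.7% to 46.2%), at 7118 loci. Transcripts with no annotated gene numbered 73149, or 45.9% (45.6% to 46.1%), at 20942 loci. Antisense transcripts numbered 5446, or 3.42% (3.33% to 3.50%). Transcripts with exactly the annotated junction chain numbered 4557, or 2.86% (2.78% to 2.94%), and 1035 of them were assembled, while the rest were models taken over from the annotation. Of all loci, 20002 (63.7%, 63.2% to 64.3%) held transcripts outside annotated genes only. These shares depend on how complete the annotation is: 8329 annotated genes had a model here. Of the 688 names of the fixed gene lists 426 had one, and of 52 Hox names 8. Known genes may therefore be among the loci outside annotated genes. With transcripts of a relative weight of 1 alone, the shares were 24.0% for new junction chains and 69.7% outside annotated genes, and with 1 transcript per locus the new junction chains made up 19.5% and antisense transcripts 5.98%. Among the loci outside annotated genes, 12111 (60.6%, 59.9% to 61.2%) were spliced, with a median largest exon number of 4, and 5979 had 5 or more exons.

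The median transcript was 2410 bases and 10 exons long for new junction chains, 2024 bases and 7 exons outside annotated genes, 2150 bases and 3 exons for antisense transcripts, and 1797 bases and 5 exons for annotated junction chains. Each of the 3 classes differed from annotated chains in length and exon number (permutation test of medians, adjusted p = 1e-05, the smallest these permutations can give). The length differences turned direction when models without an assembled transcript were left out: the class medians minus that of annotated chains were then -1687 bases for new junction chains, -2072 bases outside annotated genes and -1947 bases for antisense transcripts. The exon difference outside annotated genes then turned to -1, which did not pass (permutation p = 0.287). With 1 transcript per locus differences also turned, to -376 bases and -3 exons outside annotated genes and to -84 bases for antisense transcripts. That of -84 bases did not pass (permutation p = 0.084). With a relative weight of 1 alone none of the length differences passed (permutation p = 0.850, 0.658 and 0.678), nor did the exon differences outside annotated genes (permutation p = 0.0814) and of antisense transcripts, which turned to 1 (permutation p = 0.550). Single-exon transcripts were somewhat more frequent outside annotated genes than the 11.3% among annotated chains (Fisher's exact test, odds ratio 1.11, p = 0.0229).

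Over the whole catalogue, most transcripts were spliced. The median transcript had 2213 bases (quartiles 1210 and 3724) and 9 exons (quartiles 4 and 15), and the largest exon number was 107. With 1 transcript per locus the median was 3 exons. The 287549 distinct introns had a median of 1045 bases (quartiles 384 and 2757), and the 208695 distinct internal exons a median of 114 bases (quartiles 77 and 165). Transcripts with at least 2 exons made up 94.0% (93.8% to 94.1%). All 7917 transcripts without a strand had 1 exon.

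The next question was how many isoforms each gene had. The genes named here are those with a full symbol in the gene models and the most multi-exon isoforms. The hnRNP genes hnrnpa1, hnrnpa3 and hnrnpa2b1, whose proteins package pre-mRNA and guide splicing, had 593, 239 and 174 isoforms. The related RNA-binding genes fus and cirbp had 290 and 256 isoforms, ybx1, which encodes an mRNA-packaging protein, had 178, and fbl, which encodes the nucleolar methyltransferase fibrillarin, had 165. The keratin gene krt12 had 526 isoforms in a locus that joined 4 annotated genes, tulp3, a gene of ciliary transport, had 181, and col2a1 had 171. The isoforms of tulp3 had up to 67 exons and lay at more than 1 locus, the largest with 160 transcripts.

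At hnrnpa1, on the minus strand of scaffold GL172797 from 1971256 to 1995265, there were 803 mutually exclusive exon pairs and 151 skipped exons, 28 of them microexons. No isoform of hnrnpa1 had more than 15 exons. Exons are told apart by their exact ends, so these numbers count variants of the same exon separately. Support by at least 2 transcripts was not required. At col2a1, on the plus strand of the same scaffold from 120039 to 175772, there were 90 alternative 3 prime splice sites, 53 mutually exclusive pairs and 44 skipped exons. At cirbp there were 219 mutually exclusive pairs, 86 alternative 5 prime splice sites and 45 skipped exons. The locus of fus held 2 annotated genes and that of ybx1 held 3.

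Across 7410 spliced annotated genes with an assembled transcript, the median was 6 isoforms (quartiles 3 and 12) and the mean was 10.4. Of these genes, 6597 (89.0%, 88.3% to 89.7%) had at least 2 isoforms. With a relative weight of 1 alone the median fell to 3 isoforms and the share to 67.9%. The 160 genes with 50 or more isoforms held 19.3% of all isoforms. Isoform number rose with exon number across genes, which are not independent replicates (Spearman's rho = 0.520, permutation p = 0.0001, the smallest these permutations can give). Exon number is the largest among a gene's own transcripts. A maximum over more transcripts tends to be larger, so part of this relation may be built in. The 12111 spliced loci outside annotated genes had a median of 2 isoforms, and 54.4% (53.5% to 55.3%) had at least 2.

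By share of annotated loci, alternative first exons were the most frequent kind of variation, followed by skipped exons. By number, there were 15774 skipped exons, 15147 alternative 3 prime splice sites and 12257 additional separate first exons. For first exons, a single first exon per locus is left out of that number. Among muscle genes, tnnt3, which encodes fast skeletal troponin T, had 95 isoforms with 37 alternative 3 prime splice sites, 23 skipped exons, of which 13 were microexons, and 19 mutually exclusive exon pairs. The tropomyosin gene tpm1 had 66 isoforms with 24 alternative 3 prime splice sites, 12 mutually exclusive pairs and 11 skipped exons. The locus of tnnt3 joined 3 annotated genes. The Hox gene hoxa3 had 10 separate first exons and hoxb3 had 9. The isoforms of both span the position of another Hox gene, and whether these first exons belong to other Hox genes was not tested. All kinds of variation were more frequent at annotated genes, where annotated models add to the transcripts, than outside them.

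Loci were compared where they had at least 2 multi-exon transcripts, annotated models included. Of 7291 such loci with an annotated gene 58.0% had a skipped exon, and of 6589 outside annotated genes 46.7%. The difference was 11.3 points (Fisher's exact test, odds ratio 1.57, adjusted p = 1.23e-39). At least 2 separate first exons were present at 63.1% and 49.4%, a difference of 13.6 points (odds ratio 1.75, exact test, adjusted p = 5.70e-58), and at least 2 separate last exons at 51.1% and 39.7%. Alternative 3 prime splice sites were present at 57.4% and 47.4%, alternative 5 prime splice sites at 49.98% and 40.7%, retained introns at 29.7% and 24.4%, and mutually exclusive pairs at 10.3% and 7.60% (odds ratio 1.40, exact test, adjusted p = 2.76e-08). Among loci with 8 to 12 exons, the shares with a skipped exon were 63.3% and 58.2%, a difference of 5.17 points (odds ratio 1.24, exact test, adjusted p = 0.00211). Among loci with 2 to 5 multi-exon transcripts the differences were 5.14 points for skipped exons and 8.76 points for first exons. The 3522 annotated models without assembly all lie at annotated loci, so they may raise the shares there. No alternative without them was run for these shares.

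**Figure D1:**
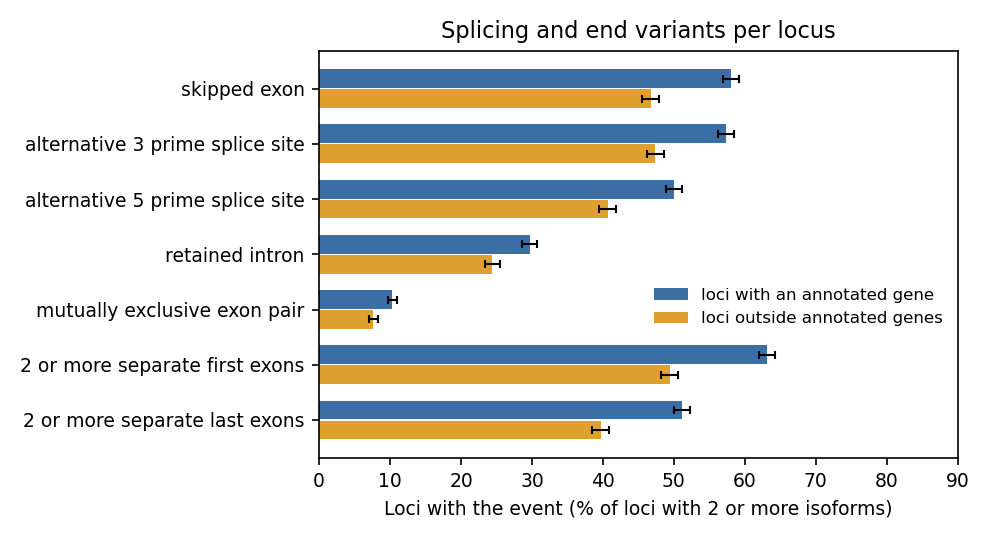
Horizontal bars give the percentage of loci with each kind of variation, and error bars are Wilson 95% intervals. Counted are 7291 loci with an annotated gene and 6589 outside annotated genes, each with at least 2 multi-exon transcripts, annotated models included. Separate first exons (63.1%) and skipped exons (58.0%) lead at annotated genes, and each blue bar is longer than its orange partner.

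Skipped exons had a length divisible by 3 more often than constitutive exons did. At loci with an annotated gene, 45.4% of 15774 skipped exons and 37.6% of 28471 constitutive exons had a length that was a multiple of 3, a difference of 7.76 points (bootstrap 95% interval over loci 6.58 to 9.02, Fisher's exact p = 7.23e-57). Outside annotated genes the shares were 49.0% of 9436 skipped exons and 39.6% of 23410 constitutive exons, a difference of 9.35 points (7.81 to 10.9, Fisher's exact p = 5.74e-54). Where skipping and inclusion each had at least 2 transcripts, the differences were 14.5 points at annotated genes and 18.2 points outside them. Skipped exons at annotated genes were also shorter, with a median of 93 bases against 122 bases (permutation p = 1e-05, the smallest possible). Microexons, such as the 13 at tnnt3 and the 4 at atp2a1, the muscle calcium pump gene, made up 4.05% of skipped and 0.428% of constitutive exons (odds ratio 9.81, exact test, p = 3.95e-169).

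**Figure D2:**
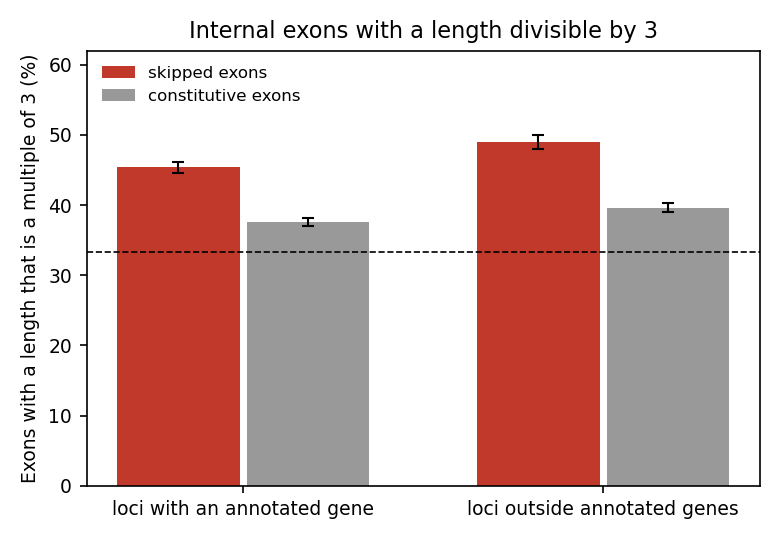
Bars give the percentage of skipped and constitutive internal exons whose length is a multiple of 3, at loci with and without an annotated gene, with Wilson 95% intervals, and the dashed line marks 33.3%. Skipped exons stand above constitutive exons at annotated genes (45.4% against 37.6%) and outside them (49.0% against 39.6%).

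The gene lists asked which tissues and processes of the embryo had a richer or poorer set of isoforms. Ribosomal protein genes, Hox genes and skeletal muscle genes had more isoforms than genes with as many exons. The 68 ribosomal protein genes had a median of 13.5 isoforms against 4 in matched lists (3.37-fold, permutation adjusted p = 0.0004, the smallest possible), led by rpl13a with 91, rps21 with 68, and rps10 and rps2 with 51 each. The 7 Hox genes, which pattern the body axis, had a median of 10 against 3 (3.33-fold, permutation adjusted p = 0.0144), led by hoxb3 with 21, hoxa3 with 18, hoxc8 with 12 and hoxc9 with 10. Of 52 fixed Hox names, 8 had a model. The hoxb3 isoforms, from 486233 to 558573, span the model of hoxb5 on the same strand. The hoxa3 isoforms, from 1414453 to 1467470, span the position of the transcript antisense to hoxa5, from 1432224 to 1433596. Both loci count as holding 1 annotated gene, so leaving out joined loci does not remove them. The 25 skeletal muscle genes had a median of 12 against 6 (2-fold, permutation adjusted p = 0.0373), led by tnnt3 with 95, tpm1 with 66, the Z-disc gene ldb3 with 46 and atp2a1 with 45.

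The calls for the Hox and muscle lists were lost without loci that join several genes (ratios 2 and 1.46, permutation adjusted p = 0.366 and 0.514) and with transcripts of a relative weight of 1 alone (ratios 0.5 and 1). The muscle call was also lost when list names were matched through synonyms too (1.63-fold, permutation adjusted p = 0.176), which was the first matching used. The ribosomal list stayed past the threshold under each alternative, with a ratio of 3 without joined loci. With means in place of medians, 6 lists passed the permutation test, the same 3 and another 3: epidermis and cement gland genes were higher (2.39-fold, adjusted p = 0.0002), and eye and lens genes (0.589-fold, adjusted p = 0.0330) and liver genes (0.544-fold, adjusted p = 0.0347) were lower.

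The other 17 lists did not pass with medians. Epidermal genes had a median of 9 against 6, with krt12 at 526, krt8 at 82, krt at 50 and krt18 at 39 isoforms. Genes of cartilage and notochord had 11.0 against 7.42, with col2a1 at 171, col9a2 at 56, the BMP antagonist gene chrd at 24 and col9a3 at 23. Mitotic cyclins and kinases had 10 against 7, with cdc6 at 29, ccne1 at 24, mcm7 at 23 and ccnb2 at 21. Maternal and germ plasm genes had 5 against 5, with cpeb1 and ddx4 at 22 each, dazl at 15 and nanos1 at 11.

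The zygotic mesendoderm and organizer list had a median of 2 against 3, with chrd at 24, gata6 at 18, the pluripotency factor gene oct25 at 13 and gata4 at 10. Neural plate and crest regulators had 4 against 3, with the paired-box genes pax2 at 37, pax6 at 20 and pax3 at 17 and tfap2b at 6. Somitogenesis genes had 4.47 against 3.16, with aldh1a2 and dlc at 10 each, cyp26a1 at 6 and dll1 at 5. Neuronal genes had 5 against 4, with the RNA-binding genes elavl4 at 22 and elavl3 at 15, and the synaptic genes stx1a at 15 and syp at 12. Motile cilia genes had 4 against 5, with rfx2 at 24, spag6 at 13, tekt3 at 9 and tekt2 at 8.

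Among organ genes, the liver list had the lowest ratio, with a median of 2 against 5 (0.4-fold, permutation adjusted p = 0.0801), and its largest members were prothrombin f2 at 14, ambp at 9, apoa1 at 7 and serpinc1 at 6. Pronephric genes had 3 against 7, with pax8 at 16, atp1b1 at 12 and slc7a9 at 3. Eye and lens genes had 3 against 4, with cryba1 at 8, arr3 at 7, and crx and cryba4 at 6 each. Cardiac genes had 5 against 5, with mybpc3 at 28, tbx5 at 9, tnni3 at 6 and myh7 at 5. Blood genes had 3 against 3, with alas2 at 15, the globin genes hba3 and hbd at 10 each and lmo2 at 4. Digestive genes had 6 against 7, with pnliprp2 at 23, prss2 at 14, and mep1a and prss1 at 8 each. Pituitary genes had 2.24 against 2.45, with trh at 1. Oxidative phosphorylation genes had 5 against 4, with ndufv1 at 28, uqcrc1 at 24, uqcrc2 at 21 and atp5a1 at 19.

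**Figure D3:**
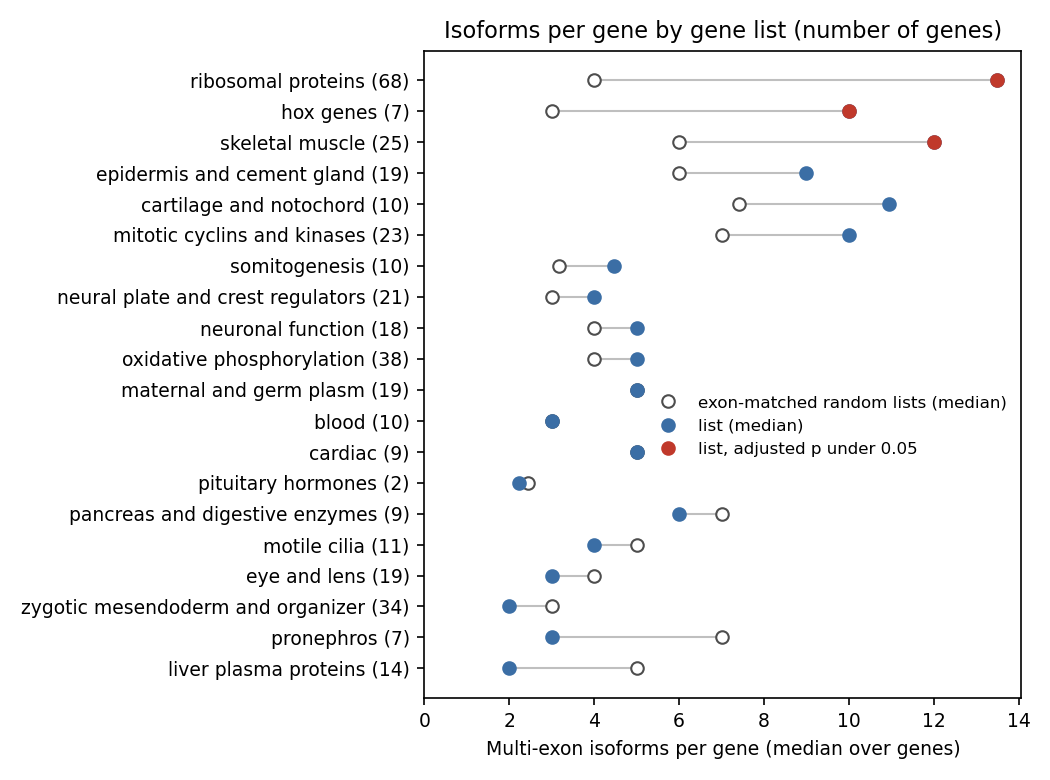
Filled points give the median number of multi-exon isoforms per gene for the 20 gene lists, with the number of genes in brackets, and open points the median of random lists matched on exon number (hidden where both coincide). Ribosomal proteins (13.5 against 4), Hox genes (10 against 3) and skeletal muscle (12 against 6) are the lists past adjusted p of 0.05.

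A further question was which annotated genes had no assembled transcript of their own among the gene models. Genes of the pancreas and gut stood out: 10 of 19 were present only as the annotated model, among them the hormone genes ins (insulin), gcg (glucagon) and sst (somatostatin), the digestive enzyme genes cela1, cpa1, ctrl, pgc, pla2g1b and prss3, and the fatty acid binding protein gene fabp2. Over all genes outside that list the share was 10.7% (Fisher's exact test, odds ratio 9.32, adjusted p = 0.000146 over 20 lists), and without loci that join several genes the odds ratio was 23.8. No other list passed. Ribosomal protein genes had the lowest share, 1 of 69 (rps27, exact test, odds ratio 0.121, adjusted p = 0.0575).

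In the other lists the genes present only as annotated models were ddx25, dnd1, gdf1 and sycp3 of the maternal list, mcm6 of the cell cycle list, and admp, fgf4, gsc, msgn1, nodal1, szl and ventx3.2 of the mesendoderm list. The regulators foxd3, neurod1, neurod4 and neurog1 of the neural list, hoxb5, mespa, the ciliary gene ccno and the ionocyte gene foxi1 were of this kind. So were mpz, vamp1 and vamp2 of the neuronal list, acta1 and myf5 of muscle, tbx20 of heart, hbg1 and rhag of blood, crybb2 and guca1a of the eye, and alb, f10 and f9 of the liver. The remaining ones were fxyd2 of the pronephros, cav1, col11a2 and matn1 of cartilage and notochord, pomc and prl.1 of the pituitary, and cox6a2 and ndufa5 of oxidative phosphorylation. In all, 895 of 8329 annotated genes (10.7%, 10.1% to 11.4%) were of this kind, 114 of 130 single-exon genes and 781 of 8199 spliced genes (exact test, odds ratio 67.7, p = 1.06e-94). It is not recorded whether reads covered these models, so this is not a measure of expression. Besides, 8284 assembled transcripts had no gene model, 4681 of them with 1 exon, and 62.4% lay inside an annotated locus. Genes of this kind, above all single-exon ones, may therefore have assembled transcripts that were not counted.

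Antisense RNA was the last class. Spliced transcripts ran opposite to ndnl2 (51 transcripts), the heme oxygenase gene hmox2 (43) and clk2 (41), and opposite to Hox genes. At clk2 they lay on the plus strand of scaffold GL174302 from 45289 to 55460 with up to 5 exons. Muscle genes had antisense transcripts at 12 of 27 members, among them the master regulator genes myod1 and myog, the actin gene actc1 and the creatine kinase gene ckm. Liver genes had them at 0 of 17.

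Altogether 1835 of 8329 annotated genes (22.0%, 21.2% to 22.9%) had spliced antisense transcripts, and with at least 3 exons required the share was 8.27%, and with a relative weight of 1 alone 14.2%. The 7917 transcripts without a strand, all with 1 exon, cannot be called antisense, so unspliced antisense RNA may be missed. The lists did not differ from other genes after adjustment: muscle at 44.4% (Fisher's exact p = 0.00897, adjusted p = 0.179), epidermis at 45.0% (p = 0.0255, adjusted p = 0.226) and liver (p = 0.0339, adjusted p = 0.226) had the smallest p-values. Of the antisense transcripts, 50.9% lay inside the gene, 24.1% crossed its 3 prime end and 19.9% its 5 prime end. An intron at the same position as one on the opposite strand was present in 59 of 5443 (1.08%, 0.841% to 1.40%).

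Long loci lay at hoxa3 and hoxb3, with antisense transcripts opposite. The hoxa3 locus, on the plus strand of scaffold GL172692 from 1410553 to 1467470, spanned 56.9 kb with 35 transcripts, 17 of them outside the annotated gene. On the opposite strand, antisense transcripts lay at hoxa5 (1 transcript) and at hoxa3, where a locus of 5.78 kb held 2 transcripts, 1 of them antisense to an exon of hoxa3. The hoxb3 locus spanned 88.2 kb with 32 transcripts, with hoxb4 antisense transcripts on the other strand, and a locus that joined hoxc8 and hoxc9 spanned 126.7 kb with 59 transcripts. These Hox loci were chosen after their values were seen.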

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

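The tests on joined loci and on skipped exons, the comparison with loci of 5 to 15 exons and the matching on exon number were chosen after the result was seen. Among transcripts that no comparison used, 7865 assembled ones with coverage above 0 were listed in the transcript table but had no gene model. Nearly all assembled transcripts have coverage above 0, so this number shows no signal beyond their presence. Of the 8284 assembled transcripts without a model, 56.5% had 1 exon and 62.4% lay inside an annotated locus.

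The scaffold GL999999, covered from 1 to 17609, carried 403 transcripts, all spliced, with 28.4 introns per kb on its minus strand against a median of 0.564 per kb over spliced loci, and its 90 plus-strand transcripts overlap exons of an annotated protein-coding gene, LOC100127682. For both strands jointly, with 656 introns, a protein-coding gene with many introns is argued against: 32.2% of the scaffold's internal exons were multiples of 3 (29.0% to 35.6%), below the 38.2% of annotated loci. The share of annotated loci counts internal exons of at most 300 bases, that of the scaffold those of every length. False junctions among abundant unspliced RNAs, as a mitochondrial genome would give, may account for the pattern: 62.4% of its introns were held by a single transcript, above 99.7% of the 291 other loci with 50 or more transcripts, which had a median of 37.1%. Against 84 such loci with 5 to 15 exons, which had a median of 41.7%, the percentile was 98.8. No other biological explanation was tested, since the design gives none, and the identity of the scaffold was not tested.

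Ribosomal protein genes had more isoforms than exon-matched genes. Loci that join several annotated genes do not account for it, since the ratio without them was 3 (permutation adjusted p = 0.002). Joins with genes that the annotation lacks are not seen by that filter, so they were not tested. Chance junctions that come with deep coverage met the test fixed beforehand: a median of 50% of the introns of these genes was held by a single transcript, above all random lists matched on isoform number, which had a median of 35%. These genes have few exons, and in lists matched on exon number as well the median was 45.9% and the percentile 78.8. Because the 2 matchings differ and read depth per gene is not known, that explanation and regulated splicing, which was not tested, cannot be told apart.

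Skipped exons were more often multiples of 3 than constitutive exons. Chance junctions of the assembly alone are argued against, since the difference was 15.7 points (14.2 to 17.1) where skipping and inclusion each had at least 2 transcripts. The smaller size of skipped exons is argued against too, with 8.12 points (6.99 to 9.09) within bins of 10 bases, and so are a few loci with very many transcripts, with 7.33 points (6.45 to 8.22) without them. Selection for an intact reading frame may be the reason, as a hypothesis found and tested on the same data, and the design holds no group that tests it.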

How the results depend on the processing

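Shares are given for new junction chains, no annotated gene and antisense, in that order, and differences are class median minus annotated chains. With at least 2 exons the shares were 48.9%, 42.8% and 3.63%, and median length was 2330 bases. With at least 500 bases the first 2 shares were 46.9% and 45.3%, median length was 2346 bases, and 88.0% of genes had at least 2 isoforms. With means, 6 lists passed for isoform number and the somitogenesis ratio turned to 0.930. Those settings were planned, except for median length and the share of genes with isoforms. List medians, with means as the alternative, had been fixed for a test by FPKM, and both were applied to isoform number only after the files were seen. The other settings were chosen after seeing the data.

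With a relative weight of 1 only, the shares were 24.0%, 69.7% and 3.95%, and the length differences, still positive, were no longer past the threshold (96, 271 and 257 bases). The exon difference outside annotated genes (5) missed it too, and that of antisense transcripts turned to 1. Median length was 1880 bases with 8 exons, the median gene had 3 isoforms, 67.9% of genes had at least 2, 1 list passed, the Hox ratio turned to 0.5, as did that of somitogenesis, cartilage and notochord turned to 0.75, and 14.2% of genes had antisense transcripts. The relative weight has no stated meaning, and the cause was not tested.

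With 1 transcript per locus the shares were 19.5%, 64.2% and 5.98%, the length differences outside annotated genes and for antisense turned to -376 and -84 bases, the exon difference outside annotated genes turned to -3, and the medians were 1480 bases and 3 exons. The difference of -84 bases was not past the threshold (permutation p = 0.084). Without loci of 50 or more transcripts the shares were 43.1%, 48.0% and 3.85%, and the medians 2107 bases and 8 exons. With assembled transcripts only, the first 2 shares were 47.0% and 46.9%, the length differences turned to -1687, -2072 and -1947 bases, the exon difference outside annotated genes turned to -1 (permutation p = 0.287, not past the threshold), and median length was 2241 bases. That setting leaves 1035 annotated chains, which shows why these differences moved. For the rest the cause was not tested. Without joined loci, 1 list passed. With names matched through synonyms too, skeletal muscle was no longer past the threshold (1.63). With at least 3 exons, 8.27% of genes had antisense transcripts.

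The skipped-exon differences, the comparisons of annotated and unannotated loci, and the digestive list kept direction and side of the threshold under every alternative run for them. None of the alternatives for splicing events left out annotated models. The FPKM alternatives could not be run because the column is no abundance, the status alternative removes nothing because all 167756 rows have status OK, and the alternatives for stages and clutches were not run. No paired analysis was possible because no column belongs to a library. Unknown depth limits every isoform count.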

Other observations

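All tests in this part were chosen after the result was seen, and families were grouped by the start of their symbols. Besides ribosomal protein genes, the SR protein genes of splicing had many isoforms: the 9 srsf genes, led by srsf2, srsf6 and srsf5, had a median of 28 against 5 in exon-matched lists (5.6-fold, permutation adjusted p = 0.0106). The 57 zinc finger genes named znf, led by znf143 and znf207, had a median of 7 against 4 (1.75-fold, permutation adjusted p = 0.0106). Collagen genes had 50.8 against 16.0 (permutation adjusted p = 0.0848), which did not pass.

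Among genes present only as annotated models, bitter taste receptor genes led, with 43 of 46 t2r genes, of which 45 have a single exon (Fisher's exact test, odds ratio 125, adjusted p = 1.15e-36). Single-exon genes as a class were also mostly of this kind, with 114 of 130. Interleukin genes and their receptors followed with 9 of 17, among them il4, il10 and il22 (odds ratio 9.43, adjusted p = 0.00118), then cytochrome P450 genes with 10 of 28, among them the aromatase gene cyp19a1 and the steroid hydroxylase gene cyp17a1 (odds ratio 4.66, adjusted p = 0.0165), and claudin genes with 5 of 9 (exact test, odds ratio 10.4, adjusted p = 0.0364). Of the 9 claudin genes, 3 have a single exon, all 3 of them present only as models (cldn3, cldn5 and cldn8.2), and the test takes no account of exon number.

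The orientation of neighbouring loci was counted in 4 ranges of distance. With 1 to 5 kb between them, 419 pairs were divergent and 811 convergent, a divergent share of 34.1% (31.5% to 36.8%, exact binomial test, adjusted p = 3.90e-28 over 16 tests). With 20 kb or more, 1346 pairs were divergent and 1028 convergent, a share of 56.7% (54.7% to 58.7%, exact test, adjusted p = 2.90e-10). Under 1 kb the share was 45.4% (exact test, adjusted p = 0.0645) and from 5 to 20 kb 49.6% (exact test, adjusted p = 0.832), and neither passed. By kind of pair, the share under 1 kb was 42.2% for pairs of 1 annotated and 1 unannotated locus (exact test, adjusted p = 0.0370), 41.2% for unannotated pairs (exact test, adjusted p = 0.0701) and 53.3% for annotated pairs (exact test, adjusted p = 0.608).

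Many spliced loci outside annotated genes may be protein-coding genes that the annotation lacks. Over 8824 such loci, 40.5% of 88602 internal exons were multiples of 3 (39.9% to 41.0%), above the 33.3% of random lengths. Antisense loci that lie inside a gene gave 34.1% of 1714 internal exons (31.5% to 37.7%), but antisense loci of 5 or more exons gave 38.1% (36.4% to 39.8%), so the contrast depends on which antisense loci are taken, and short loci of 3 or 4 exons outside annotated genes gave 38.3% (36.7% to 39.9%). The 40.5% and 34.1% count internal exons of every length, the 38.1% and 38.3% only those of at most 300 bases. The sequence needed to look for reading frames was not used here.

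Whether digestive and pancreatic genes were present only as annotated models because they have fewer exons was tested. The list had 10 such members, against a mean of 2.07 in random lists matched on exon number (permutation p = 5e-05, the smallest that 20000 random lists can give), which argues against that explanation. Whether these genes were little transcribed up to the last stage was not tested.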
